A study of Mus musculus with 471 samples.

How the data were processed

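The deposited table held read counts per Ensembl gene for 471 libraries, and per the labels each library came from RNA of sorted spleen cells, amplified to full-length cDNA and sequenced as single-end reads. Reads were trimmed with Trimmomatic 0.32, aligned with STAR 2.7.1 to mm10 (GRCm38) and handled in R 3.2.3, per the submitters' processing notes, which state neither the counting program nor its filters. The counts were whole numbers with no normalization, and no strand or multi-mapping rule is recorded. Of 54232 genes 54079 had a symbol in the reference table and 153 did not. No pair of libraries of 1 group (1767 pairs) had the same counts within sampling noise, the lowest chi-square per degree of freedom being 6.66 over genes of at least 20 counts. Per the labels' protocols, cells came from mice of 8 to 12 weeks, macrophages and CD8 T cells were cultured for 20 h in all, and IFN-beta was given for 20 h or, after 18.5 h without it, for the last 1.5 h (16 libraries of research group MM are titled 20 h 30 min), and dendritic cells were pooled from littermates.

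The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Counts were scaled by edgeR's TMM factors, and genes passing filterByExpr for the groups of a fit were tested with edgeR 4.0.16 (quasi-likelihood F test, robust), with the research group as a covariate and a Benjamini-Hochberg adjusted p under 0.05. Fresh libraries were fitted per cell type: 16928 genes in CD8 T cells (75 libraries), 17633 in macrophages (58), 15188 in NK cells (30), 14142 in B cells (18) and 10996 in dendritic cells (14). Cultured libraries, with 2-by-2 interaction terms of genotype and IFN-beta over both times in 1 F test, gave 32926 genes in CD8 T cells, 28670 in macrophages and 12315 in NK cells, and fits of cultured with fresh libraries 29311, 26599 and 15634. The interaction of culture was mutant against wildtype in culture minus the same difference in fresh cells. The 2 Stat6-ko B cell libraries and the single Stat5-ko cultures were not tested. Stat2-ko had 1 untreated macrophage culture and 1 CD8 T cell culture at 1.5 h, each assumed to vary like the other groups. Log2 fold changes and CPM were computed here. The alternatives were DESeq2 1.42.0 and its size factors, no filter on low counts, no research group term, the batch as a replicate block, and each replicate left out in turn; the fits of the compared groups only (the groups of the comparison within the mutant's research groups), those without libraries over 40% mitochondrial counts and those with a block in the compared groups were chosen after seeing the data.

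The labels name a batch for every library but not whether it is a day or a run. Counted per cell type, fresh or cultured, 106 of 136 batches with a mutant also held wildtype, and there the batch pairs the samples, while fresh Irf9-ko CD8 T cells had no wildtype in their batches. Deviations from group means correlated more within a batch (median r 0.0200 in NK to 0.410 in B cells when fresh, 0.574 in cultured NK cells) than across (-0.0222, -0.135, -0.278).

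The 26 lists, 47 genes in the ISG list, cover type I ISGs; interferon-gamma-type GTPase and GAS genes; MHC class I and antigen processing; MHC class II; inflammatory cytokines and NF-kB feedback; red pulp macrophage and iron handling; cytotoxic and effector genes; naive T cell genes; targets of STAT3, STAT4 with interleukin-12, STAT5 and STAT6; proliferation; immediate early and heat shock genes; cholesterol synthesis; glycolysis; mitochondrially encoded genes; and markers of T cells, CD4 and regulatory T cells, B cells, plasma cells, NK cells, macrophages, neutrophils, dendritic cells and erythroid cells. They share members, such as Gzma and C1qc. Each list was tested with fry (limma 3.58.1) on log2 CPM with a prior count of 2 in the same design, adjusted over the lists. Named genes were the targeted genes, listed genes past the threshold (up to 4 per list by size) and up to 10 higher and 10 lower genes with the largest fold among called genes of at least 5 CPM whose mutant libraries all lay on 1 side of their research group's wildtype mean, taken in rank order; predicted genes, antigen receptor segments and sex-linked genes were left out, and so were genes with 1 to 3 counts in a group. A listed gene given no value may have passed.

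Simulated counts with 200 changed genes per comparison gave the power of the fits, on 4000 genes for cultured CD8 T cells and macrophages. In the fit of fresh CD8 T cells, Tyk2-ko against wildtype, 56% of genes changed 2-fold and 94% of those changed 4-fold were recovered, with 13.3% false calls; in macrophages 46% and 90% (16%), in NK cells, Stat5-hyp against wildtype, 2% and 27% (21.6%), in B cells, Stat5-ko, 1% and 29% (14.3%), and in dendritic cells, Tyk2-ko, 0% and 7% (3 of 10 calls false). In NK cells at 20 h of IFN-beta 19% and 89% were recovered (9.24%), and for the CD8 T cell Stat1-ko difference between culture and fresh 1% and 23% (4%), where 7 of 50 unchanged lists had p under 0.05, more than 5%. In cultured macrophages 5% and 6% were recovered at 20 h of IFN-beta with 66.7% false calls, and 0% for the Tyk2-ko interaction, so single genes there carry little weight. DESeq2's test made 419 false calls of 483 for Stat5-hyp NK cells, and its counts are given for comparison only.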

Results

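The series held 471 RNA-seq libraries of mouse spleen cells in 114 groups, each a cell type, genotype and treatment. The 5 sorted cell types were, per the labels, CD8 T cells, macrophages, natural killer (NK) cells, B cells and dendritic cells. Cells were frozen for RNA after sorting (fresh), cultured untreated, or cultured with interferon beta (IFN-beta), a type I interferon, for 1.5 h or 20 h. CD8 T cells gave 75 fresh, 45 cultured, 40 IFN-beta 1.5 h and 44 IFN-beta 20 h libraries. Macrophages gave 58, 39, 39 and 40 in the same order, and NK cells 30, 9, 9 and 9. B cells gave 20 fresh libraries and dendritic cells 14. The 13 genotypes were Wildtype (180 libraries), the losses labelled Irf9-ko, Stat1-ko, Stat2-ko, Stat3-ko, Stat4-ko, Stat5-ko, Stat6-ko and Tyk2-ko, and 4 others. These were the single Stat1 isoforms Stat1a-only and Stat1b-only, Tyk2-inact (inactivated by its label) and Stat5-hyp (a changed Stat5b by title code). Fresh Stat1-ko pooled title codes STAT1KO and STAT1VAV (cultured STAT1KO only), dendritic Tyk2-ko TYK2CMV and TYK2KO. STAT proteins and IRF9 are transcription factors, and TYK2 is a kinase bound to the type I interferon receptor. Libraries came from 7 research groups in 71 batches.

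Total counts ran from 993133 to 21834855 per library (median 10541423), and a median of 13592 genes had a count. Cultured macrophages had a median of 8151 detected genes against 17642 when fresh, and CD8 T cells 13037 against 15935. Mitochondrially encoded genes took 0.601% to 97.3% of the counts (median 6.00%). They took over 40% in 25 CD8 T cell libraries, most of them Irf9-ko or Stat2-ko and all but 2 from the research group coded TD, and in 5 cultured macrophage libraries, treated or not. Each fold below is a log2 fold change ± its standard error with an adjusted p from edgeR's quasi-likelihood test over all genes tested in that cell type, unless a CPM (counts per 1000000 in the library) is given. Gene lists were tested with fry, adjusted over the lists measured (24 to 26), which asks whether a list's genes move on balance one way and makes no comparison with other genes. A count of listed genes is over all genes tested, followed by the count adjusted over the list alone. Genes of near-identical families (Ifit, Oas1, Gbp, Tgtp1 with Tgtp2, H2-Q6 with H2-Q7) were uncertain one by one, since shared reads could be split between them. Where all libraries of 1 side were at 0 counts, the fold is a bound from 3 counts over that group, which covers counting error only.

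**Figure D1:**
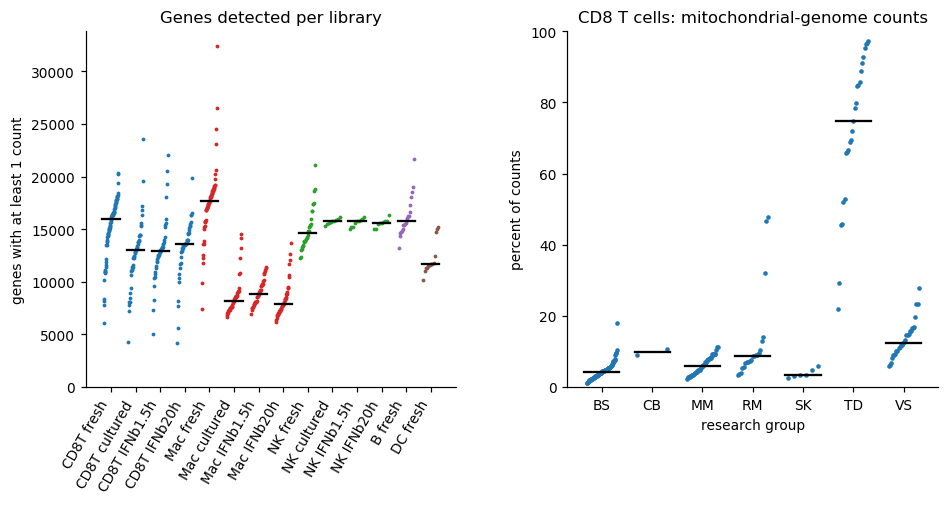
The left panel shows genes detected per library by cell type and treatment, with bars at the medians. The right panel shows the percent of counts from mitochondrially encoded genes in CD8 T cell libraries by research group.

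Targeted genes were read as whole-gene counts (mean CPM ± SD in fresh cells), which cannot check a deletion of part of a gene. Stat1 (chromosome 1, 52119440 to 52161865, mm10) stood at 1.21 ± 0.624 in Stat1-ko macrophages (n = 3) against 69.6 ± 21.1 in wildtype (n = 21), and at 4.23 ± 0.639 (n = 3) against 158 ± 50.9 (n = 28) in CD8 T cells. In the isoform lines it stood at 31.6 ± 0.369 (Stat1a-only) and 13.4 ± 4.35 (Stat1b-only) in macrophages and at 112 ± 16.7 and 19.3 ± 3.45 in CD8 T cells. Stat2 (chromosome 10, 128270559 to 128292849) had 0.774 against 35.3 CPM in Stat2-ko macrophages and 1.4 against 23.8 in CD8 T cells. Irf9 (chromosome 14, 55603571 to 55610030) stood at 38.3 ± 15.7 in Irf9-ko macrophages against 89.1 ± 25.8, and at 15.0 ± 25.8 in CD8 T cells (n = 3, from 0 to 44.8) against 145 ± 54.1. Stat3 (chromosome 11, 100885098 to 100939540) had 23.5 against 120 CPM in Stat3-ko macrophages, 23.9 against 127 in CD8 T cells, 29.7 against 97.8 in NK cells and 16.4 against 72.9 in B cells. Stat6 (chromosome 10, 127642986 to 127660957) had 21.4 against 101 CPM in Stat6-ko macrophages, 33.1 against 122 in CD8 T cells and 16.3 against 63.9 in NK cells. Stat5a (chromosome 11, 100859351 to 100885169) had 0.0197 against 22.5 CPM in Stat5-ko macrophages, 1.91 against 46.1 in CD8 T cells and 0.151 against 14.2 in B cells. Stat5b (chromosome 11, 100780731 to 100850724) had 0.0397 against 41.1, 8.49 against 59.6 and 0.0394 against 28.2. In Stat5-hyp cells Stat5b stood at 39.97 CPM in CD8 T cells (wildtype 59.6), 28.4 in B cells (wildtype 28.2) and 42.2 in NK cells (wildtype 23.8). Whole-gene counts were not lower for Stat4 (chromosome 1, 51987148 to 52107189) in Stat4-ko macrophages (12.5 against 8.29 CPM) or CD8 T cells (103 against 104). For Tyk2 (chromosome 9, 21104068 to 21131243) they stood at 42.6 in Tyk2-ko and 46.4 in Tyk2-inact macrophages against 32.5 ± 14.4, and at 31.3 and 27.7 in CD8 T cells against 37.1 ± 22.3.

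Cd8a, a CD8 chain, had 998 ± 261 CPM in CD8 T cells (n = 28), 196 ± 102 in dendritic cells (n = 4) and 17.9 in macrophages. Adgre1, F4/80, had 658 ± 347 in macrophages (n = 21) and 243 ± 250 in dendritic cells. Ncr1, an NK receptor, had 2590 ± 1060 in NK cells (n = 14), Cd19 of the B cell receptor complex 998 ± 321 in B cells (n = 9), and Itgax, CD11c, 299 ± 106 in dendritic cells and 257 in macrophages. Macrophage libraries held plasma cell markers (median of list means 492 CPM), and dendritic cell libraries NK (155) and macrophage markers (157), as high as their own (153).

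In cultured wildtype CD8 T cells at 1.5 h of IFN-beta (16 against 17 libraries) the antiviral effectors Mx2 (8.85 ± 0.49, adjusted p = 4.4e-36), Ifit1 (8.54 ± 0.37), Cmpk2 (8.26 ± 0.48) and Rsad2 (7.70 ± 0.40) rose, with the T cell-attracting chemokine Cxcl10 (6.26 ± 0.44). Of the 47 type I interferon-stimulated genes (ISGs) 45 rose (46 adjusted over the list alone; median 4.29, fry adjusted p = 5.6e-34), and of 21 interferon-gamma-type GTPase and GAS genes 19 (20; 4.75, 2.3e-25). STAT5 targets rose (8 of 12; 2.12, 1.5e-10), among them Cish (5.36 ± 0.62), a cytokine signaling inhibitor, and Il2ra (3.35 ± 0.58), the interleukin-2 receptor alpha chain. So did STAT4 and interleukin-12 targets (5 of 8, 7 adjusted over the list alone; 3.12, 1.3e-07) with Il12rb2 (4.85 ± 0.84), and STAT3 targets (4 rose and 1 fell of 10; 1.06, 5.0e-05) with Socs3 (3.48 ± 0.62). Id3, a regulator of naive and memory T cells, fell (-4.16 ± 0.52, adjusted p = 2.8e-10). Here 910 genes changed (740 higher).

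At 20 h all 47 ISGs were higher in CD8 T cells (median 4.70, 3.9e-38), led by Ifi44 (9.08 ± 0.67), Mx2 (8.91 ± 0.49) and Mx1 (8.55 ± 0.56), and Cxcl10 stood at 7.88 ± 0.47. MHC class I and antigen processing genes rose (10 of 17, 15 adjusted over the list alone; 1.38, 5.6e-05), as did the cytotoxic protease Gzmb (5.41 ± 0.90, adjusted p = 5.5e-06), the memory marker Ly6c2 (5.69 ± 0.56) and Bst2, which tethers budding virus (4.41 ± 0.44). Igfbp4 of the naive list fell (-2.96 ± 0.67). Of 438 changed genes 354 were higher.

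In macrophages (15 against 15 libraries) Ifit2 (9.93 ± 1.07, adjusted p = 3.8e-16), Cmpk2 (8.66 ± 1.05) and the chemokine Cxcl9 (11.29 ± 1.45) rose at 1.5 h, with 37 of 47 ISGs (43 adjusted over the list alone; median 4.67, fry adjusted p = 1.4e-21) and 16 of 21 GAS genes (17; 5.13, 2.7e-24). At 20 h 44 ISGs were higher (46; 5.12, 6.3e-25), the GTPase Irgm1 at 6.69 ± 1.03 and Cxcl10 at 6.30 ± 0.82, and the peptide transporter gene Tap1 at 2.29 ± 0.76. Over all genes 2513 changed at 1.5 h (1271 higher) and 2097 at 20 h (1101 higher). The counts were 120 (96 higher) and 113 in a fit of the compared groups only and 100 and 133 in the same fit with the replicate block.

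In NK cells (3 against 3) Ifit1 (10.38 ± 0.77, adjusted p = 2.0e-10), Rsad2 (9.27 ± 0.50) and Cxcl10 (8.66 ± 0.68) rose at 1.5 h with 44 ISGs (46 adjusted over the list alone; median 4.08, 6.2e-14). So did Ifng, the cytokine interferon gamma (2.96 ± 0.59), and Jun, an immediate early factor (3.51 ± 0.30). At 20 h 46 ISGs (47; 4.92, 8.3e-15) and 10 MHC class I genes (12; 1.30, 3.3e-06) were higher, Gzmb stood at 2.52 ± 0.53 and the chemokine Ccl5 at 2.41 ± 0.46. Of 23 proliferation genes 10 fell (17; -1.39, 0.015), among them Ccnb1 (-2.80 ± 0.70), a mitotic cyclin. Ccnb1 did not pass without IFN-beta replicate 1 (adjusted p = 0.059) or 3 (0.077) or untreated replicate 3 (0.069). IFN-beta changed 590 genes at 1.5 h (387 higher) and 979 at 20 h (607 higher), and 1169 and 2578 with the replicate block. Proliferation had an adjusted p of 0.098 in a fit of the compared groups only.

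Cultured wildtype CD8 T cells, against fresh ones, lost ISG expression (29 of 47 fell, 36 adjusted over the list alone; median -1.64, 1.2e-11), Rtp4 at -3.14 ± 0.36 and Dhx58, an RNA sensor, at -3.24 ± 0.48, while Pim1, a survival kinase (2.96 ± 0.36), and Il7r, the interleukin-7 receptor (1.80 ± 0.32), rose. GAS genes fell (10 of 21, 1 rose, -1.08, 4.3e-07), as did MHC class I (4 of 17, -0.31, 0.027), MHC class II (7 of 8, -3.10, 8.6e-09) and cytotoxic genes (10 of 22, -1.55, 4.3e-07) with Gzma (-4.74 ± 0.88). Proliferation (9 of 23, -1.90, 3.8e-06), immediate early and heat shock (9 of 18, -1.52, 6.5e-07) and glycolysis genes (6 of 13, -0.69, 8.7e-05) fell. So did STAT3 (3 of 10, -0.61, 0.0020), STAT4 (2 of 8, -1.82, 1.3e-05), STAT5 (2 of 12, 1 rose, -0.96, 4.3e-05) and STAT6 targets (5 of 9, -3.73, 1.0e-05). Markers of other cells fell too: red pulp macrophage genes (15 of 20, -4.11, 8.6e-09) with C1qc (-6.83 ± 0.90), macrophage (9 of 10, -4.99, 8.6e-09), neutrophil (9 of 10, -5.55, 0.0019), and B cell genes (9 of 10, -2.75, 5.4e-08). The same held for NK (8 of 10, -3.00, 7.4e-09), dendritic (4 of 10, -2.52, 4.3e-07), erythroid (7 of 8, -3.66, 8.8e-04), plasma cell (1 of 6, -1.31, 0.020) and CD4 and regulatory T cell markers (1 of 6, -1.32, 2.4e-05). Here 2587 genes changed (1084 higher; 17 against 28 libraries).

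Cultured macrophages lost markers of resident macrophages, Mrc1, the mannose receptor (-8.63 ± 0.98), and Mertk, an engulfment receptor (-8.27 ± 0.99), with 13 of 20 red pulp genes lower (median -3.75, 2.7e-24), 15 of 23 proliferation genes lower (-4.96, 3.5e-22) and 14 of 17 MHC class I genes higher (2.08, 0.0029), H2-Q7 by 3.99 ± 0.65. Mitochondrially encoded genes rose (6 of 6; 4.04, 5.8e-10), and STAT6 targets fell (6 of 10, 1 rose; -5.56, or -5.34 with genes at 0 set to their bound; 5.9e-33). The GAS, STAT5, STAT4, MHC class II, B cell and plasma cell lists had a median above 0 (0.30, 1.10, 0.07, 0.06, 1.89 and 2.05) and a fry test pointing down. Of 10307 changed genes 4193 were higher, 3120 with DESeq2's size factors (7047 lower), and a fit of the compared groups only called 5304. In NK cells culture raised cholesterol synthesis (12 of 18, 16 adjusted over the list alone; 3.39, 1.1e-06) with Fdps (5.65 ± 0.83) and glycolysis (10 genes; 1.93, 1.4e-04) with Hk2 (4.55 ± 1.02). It lowered the quiescence factor Klf2 (-3.95 ± 0.45), the NK maturation marker Klrg1 (-4.86 ± 0.48) and 10 ISGs (1 rose; -1.65, or -1.38 with genes at 0 set to their bound; 0.0019). It changed 2169 genes there (1093 higher; 1288 of 2158 with DESeq2's size factors; 3 against 14 libraries).

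Without Stat1, fresh CD8 T cells (3 against 28 libraries, 9 of the same research groups, BS and TD) had lower Ifit1 (-8.58 ± 1.23, adjusted p = 4.7e-06), Rtp4 (-7.53 ± 1.11), Ifit3 (-5.79 ± 0.85), Usp18, which removes ISG15 (-5.14 ± 0.79), the GTPase Igtp (-3.13 ± 0.49) and the MHC class I gene H2-Q7 (-2.77 ± 0.59). Of the ISGs 10 fell (31 adjusted over the list alone; median -2.41, 1.3e-11), of the GAS genes 5 (13; -1.62, 9.7e-06) and of the MHC class I genes 2 (8; -1.28, 3.0e-05). Stat1 itself stood at -5.53 ± 0.52. H2-Q7 did not pass without Stat1-ko replicate 1 (adjusted p = 0.92) or 2 (0.89). The count was 20 genes (19 lower; 10 without Stat1-ko replicate 1), 136 in the compared groups only and 56 with the replicate block (47 lower). The MHC class I list had an adjusted p of 0.084 when both changes were made.

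Stat1-ko macrophages (3 against 21) had lower Oas1a, an RNA-sensing synthetase (-8.27 ± 0.77), Rtp4 (-8.09 ± 0.65, adjusted p = 2.4e-14), Ifi27l2a (-5.73 ± 0.55), Tgtp2 (-5.26 ± 0.71), Cxcl10 (-3.95 ± 0.96) and H2-K1 (-1.63 ± 0.20). They had higher Ccl17 (3.71 ± 0.63, adjusted p = 9.3e-05), Ccl24 (2.00 ± 0.49) and Mgl2 (2.86 ± 0.47), which interleukin-4 induces through STAT6. ISGs (22 of 47, 37 adjusted over the list alone; -2.69, 1.9e-11), GAS genes (7 of 21, 14; -1.48, 3.3e-05) and MHC class I genes (5 of 17, 8; -1.05, 3.3e-05) fell, and STAT6 targets rose (2 of 10, 3; 0.73, 0.020). Here 102 genes changed (53 higher, 49 lower), 313 with the replicate block (113 higher), and 29 without Stat1-ko replicate 1. Without replicate 1, Cxcl10 (-3.30, adjusted p = 0.72), Ccl24 (1.44, 1) and Ccl17 (2.20, 1) did not pass, nor did Cxcl10 (0.15) and Ccl24 (0.25) without replicate 3, and Cxcl10 stood at -6.38 without replicate 2. The STAT6 call had an adjusted p of 0.096 in the compared groups only and 0.65 with the block there, where MHC class I had 0.097.

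In CD8 T cells edgeR called 0 genes in Stat1a-only (4 libraries; 187 at an unadjusted p under 0.05, and 14 by DESeq2) and 1 in Stat1b-only, Stat1 itself (-3.31 ± 0.45, adjusted p = 3.6e-06). With the replicate block in the compared groups it called 49 and 34, and GAS genes passed in Stat1a-only (higher, 0.045) and Stat1b-only (lower, 0.014), as did MHC class I in Stat1b-only (lower, 0.040). Stat1a-only CD8 T cells had more Iigp1 (9.30 ± 1.44, adjusted p = 1.0e-04) and H2-Q6 (2.94 ± 0.61) than Stat1b-only cells, with Stat1 at 2.55 ± 0.45 the 3 genes called (145 in the compared groups only, 19 with the replicate block). They also had higher GAS (1 of 21, 5 adjusted over the list alone; 1.19, 0.014) and MHC class I lists (0.87, 0.014). H2-Q6 did not pass when any 1 of the 7 libraries was left out (adjusted p from 0.061 to 1), nor Stat1 without Stat1b-only replicate 1 (0.086) or 2 (0.15). In macrophages Stat1a-only called 9 genes (8 higher, 7 of them immunoglobulin segments, transcripts of B or plasma cells; 2 without Stat1a-only replicate 1), Stat1b-only 1, Stat1 (-2.57 ± 0.39, adjusted p = 2.7e-04; 6 genes with the block). Stat1a-only against Stat1b-only called 0 (531 at an unadjusted p under 0.05, 46 by DESeq2, 118 with the block, where the ISG list had an adjusted p of 0.0050).

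Without Stat2, macrophages (3 against 21) lost Ifi27l2a (-7.81 ± 0.68, adjusted p = 7.2e-12), Rtp4 (-7.66 ± 0.72), Oas3 (-8.04 ± 1.02) and Oasl2 (-4.74 ± 0.84), Oasl1 was at least 102-fold lower, and 16 ISGs fell (31 adjusted over the list alone; -2.26, 4.2e-13). The count of 342 (307 higher) was 19 both with the block (16 lower) and in the compared groups only. It was 102 without Stat2-ko replicate 3 and 3980 without replicate 1. Oasl1 did not pass without replicate 3 (adjusted p = 0.063), and Oasl2 stood at -8.26 and Rtp4 at -12.91 without replicate 1. In CD8 T cells Stat2-ko lowered Ifit1 (-7.35 ± 1.59) and Rtp4 (-6.91 ± 1.56), Mx2 was at least 75.5-fold lower, and 11 ISGs fell and 3 rose (21 and 5; -1.79, 1.7e-12; 0.084 in the compared groups only). In the same libraries mt-Nd2 of the mitochondrial genome (3.96 ± 0.85), the T cell markers Cd8a (2.64 ± 0.40) and Cd3g (2.46 ± 0.40) and Klf2 (3.06 ± 0.72) were higher, 6 of 6 mitochondrially encoded genes among them (3.81, 0.0029; 0.88 with the block). These rested on single libraries: without Stat2-ko replicate 3 mt-Nd2 (1.98, adjusted p = 0.22), Cd8a (0.56, 0.45) and Cd3g (0.97, 0.14) did not pass, nor Klf2 without replicate 2 (0.35, 1), nor Mx2 without any 1 of the 3 (0.11 to 0.24). Of 1599 called genes (1465 higher), 31 were called with the block and 0 in the compared groups only, 391 without Stat2-ko replicate 3 and 3166 without replicate 1.

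Without Irf9, CD8 T cells (3 against 28, 2 of the same research group) had 20 lower ISGs (28 adjusted over the list alone; median -4.84, or -3.58 with the 14 genes at 0 set to their bound; 1.0e-14). In these cells Ifit1 was at least 444-fold and Rtp4 at least 432-fold lower, and the GTPase Gbp7 fell (-3.03 ± 0.78). Outside these lists Hmgcr of cholesterol synthesis fell (-6.71 ± 1.60), Gzmb was at least 350-fold lower and Fut4 rose (7.21 ± 1.29). The count was 1672 (648 higher; 396 of 1674 with DESeq2's size factors), 0 in the compared groups only and 1055 without Irf9-ko replicate 1. Fut4 stood at -0.08 (adjusted p = 1) and Gzmb did not pass (0.075) without replicate 1, and Gbp7 stood at -10.15 without replicate 2. Irf9-ko macrophages (3 against 21) had 17 lower ISGs (23; -1.37, 4.7e-09), with Oasl1 at least 138-fold and Ifi44 at least 107-fold lower. Skeletal muscle genes were higher in the same libraries, Pvalb at least 3210-fold, and the contractile proteins Tnnt3 (10.20 ± 1.27), Acta1 (9.61 ± 1.08) and Mylpf (7.71 ± 1.09). They rested on Irf9-ko replicate 3: without it Acta1 stood at 1.34 (adjusted p = 0.52), Mylpf at 1.80 (0.40) and Tnnt3 at 2.89 (0.19), and Pvalb did not pass (0.60). Here 905 genes changed (299 higher), 3225 with the replicate block, 5 in the compared groups only, 261 without Irf9-ko replicate 3 and 1696 without replicate 2.

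Both Tyk2 mutants had lower ISG lists in CD8 T cells, macrophages, NK cells and dendritic cells. In CD8 T cells Tyk2-inact (7 against 28) lowered Oasl1 (-9.16 ± 1.0), Usp18 (-6.35 ± 0.62, adjusted p = 1.5e-12), Ifi27l2a (-6.06 ± 0.55) and Ifit3 (-5.53 ± 0.60), and Tyk2-ko (7 against 28) Oasl1 (-9.09 ± 1.01), Usp18 (-4.71 ± 0.55) and Ifit3 (-6.15 ± 0.65). In each mutant 11 ISGs fell (22 and 20 adjusted over the list alone; -1.14 with 2.5e-08, and -0.98 with 7.8e-08). Tyk2-inact changed 133 genes (102 lower; 6 in the compared groups only, 43 with the replicate block) and Tyk2-ko 134 (99 lower; 5 and 65). In macrophages (5 against 21 each) Rtp4 stood at -7.28 ± 0.49 in Tyk2-inact and -6.33 ± 0.46 in Tyk2-ko, Oas1a at -8.63 ± 0.63 and -8.67 ± 0.64. Here 21 and 20 ISGs fell (34 and 35; -1.67 with 1.4e-09, and -1.64 with 2.4e-09). Of 35 genes in Tyk2-inact 33 were lower and of 34 in Tyk2-ko 31. Fits of the compared groups only called 85 and 70, and the block 126 and 150. In NK cells (3 against 14) Usp18 fell in Tyk2-inact (-4.99 ± 0.75, adjusted p = 0.0011) and Tyk2-ko (-3.85 ± 0.66, adjusted p = 0.026), with 2 and 1 ISGs (10 and 4; -1.24 with 0.0022, and -1.003 with 0.018; 0.065 and 0.23 in the compared groups with the replicate block). The chaperone Hspa8 fell in Tyk2-inact (-2.91 ± 0.40). The counts were 12 and 11 (7 and 5 lower; 13 of 19 higher in Tyk2-ko with DESeq2's size factors), 84 and 169 with the block, 2 and 5 in the compared groups only, and 0 and 0 with both (edgeR; 1073 and 1286 at an unadjusted p under 0.05). The Tyk2-ko count was 0 without Tyk2-ko replicate 1 and the Tyk2-inact count 3 without Tyk2-inact replicate 2. Usp18 in Tyk2-ko did not pass without replicate 1 (adjusted p = 0.062) or 3 (0.069), and stood at -6.51 without replicate 2. In dendritic cells, where 4 wildtype libraries stood against 4 Tyk2-inact and 6 Tyk2-ko libraries, Ifi27l2a fell in both (-9.52 ± 1.25, adjusted p = 3.0e-04, and -5.99 ± 0.77), and Oasl2 in Tyk2-ko (-9.32 ± 1.55), the 1 and 2 genes called (4 and 7 with the block). Their ISG lists fell (9 and 16 genes adjusted over the list alone; 35 measured; -1.87 with 9.0e-04, and -1.50 with 4.7e-04), and in Tyk2-ko so did MHC class I genes (-0.61, 0.044; 0.059 in the compared groups only; in Tyk2-inact 0.12, and 0.018 with the block). Dendritic cell markers rose in the same Tyk2-ko libraries (0.54, 0.047; 0.065 in the compared groups only). With the block in the compared groups the Tyk2-inact ISG list had an adjusted p of 0.080, with 0 genes called (406 at an unadjusted p under 0.05).

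Between Tyk2-ko and Tyk2-inact the ISG list had adjusted p values of 0.97 in CD8 T cells, 0.99 in macrophages and NK cells and 0.93 in dendritic cells. Single genes numbered 541 in CD8 T cells (273 higher; 0 in the compared groups only, 333 with the replicate block, 132 of them higher), 1 in macrophages (86 at an unadjusted p under 0.05), 1 in NK cells (10 with the block) and 0 in dendritic cells (625 at an unadjusted p under 0.05, and 1346 by DESeq2).

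**Figure D2:**
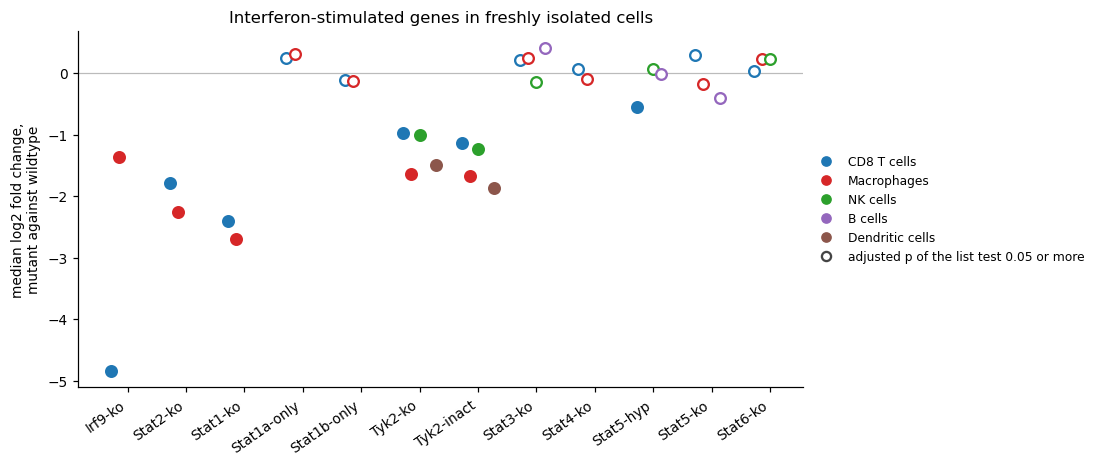
Each point is the median log2 fold change of the ISGs (47, or 35 measured in dendritic cells) in 1 fresh mutant against wildtype, colored by cell type, and open where the adjusted p of the list test was 0.05 or more.

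In Stat5-hyp CD8 T cells (5 against 28 libraries) feedback genes of STAT5 rose, Socs2 (5.72 ± 0.61, adjusted p = 8.6e-12), Cish (3.88 ± 0.74) and Il2ra (3.05 ± 0.62), with 6 of 12 STAT5 targets (median 1.28, 2.5e-06). Cytotoxic effectors rose (14 of 22, 18 adjusted over the list alone; 2.67, 5.3e-04), among them Gzmb (5.49 ± 0.86), the NK receptor Klrc1 (5.00 ± 0.80) and Ccl5 (3.77 ± 0.80). So did proliferation genes (13 of 23, 19; 2.40, 0.013) with Mki67 (3.52 ± 0.81) and Bub1 (3.59 ± 0.83). Naive genes fell (4 of 13, 7; -0.82, 0.0031), including the transcription factor Lef1 (-1.46 ± 0.32) and the homing receptor Ccr7 (-1.40 ± 0.35), as did ISGs (7, 9; -0.56, 0.0061) with Ifit1 (-2.34 ± 0.58). Macrophage genes in these libraries were lower, 5 of 10 markers (-3.45, 0.29) with Vcam1 (-6.04 ± 1.51) and C1qa (-3.72 ± 0.99). The count was 1027 (607 higher), 448 in the compared groups only and 1897 with the replicate block (1068 higher). With both changes ISGs had an adjusted p of 0.097, naive genes 0.090 and proliferation 0.089.

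In Stat5-hyp NK cells (4 against 14) the STAT5 targets Socs2 (2.59 ± 0.58) and Bcl2, a survival factor (0.996 ± 0.27), rose (list 0.40, 0.024; 0.075 with the replicate block). Meanwhile 7 of 10 NK markers fell (8 adjusted over the list alone; -1.22, 1.1e-04) with the receptors Klra8 (-1.28 ± 0.24) and Klra4 (-1.23 ± 0.28). Genes of other cells were higher in the same libraries: the macrophage genes Csf1r (5.73 ± 0.83), Adgre1 (8.99 ± 1.63) and Treml4 (5.40 ± 0.64), 5 of 9 macrophage markers (3.57, 0.024; 0.070 with the block), and the T cell genes Cd8a (5.64 ± 0.99) and Cd3e (5.46 ± 1.20). Without Stat5-hyp replicate 3 Cd3e stood at 0.49 (adjusted p = 0.97), Cd8a at 3.41 and Socs2 at 1.89 (0.077), Adgre1 did not pass without replicate 1 (0.061), nor Bcl2 without replicate 1 (0.095), 3 (0.053) or 4 (0.052). Of 545 called genes 477 were higher, 232 in the compared groups only and 358 without Stat5-hyp replicate 1. NK markers in the compared groups had an adjusted p of 0.074 and the STAT5 list 0.10. In B cells Stat5-hyp (3 against 9) called 4 genes (14 with the block, 0 without Stat5-hyp replicate 2 or 3), among them Adm (-4.80 ± 0.79) and Tmc3 (-6.32 ± 1.12), both lower. GAS genes rose as a list (0.72, 0.020; 0.41 in the compared groups with the block). Neither passed when any 1 of the 3 libraries was left out (adjusted p from 0.089 to 0.30).

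Without Stat5, CD8 T cells (3 against 28) had fewer naive transcripts (3 of 13, 7 adjusted over the list alone; -0.94, 3.1e-05; 0.29 in the compared groups only), with Ccr7 at -1.58 ± 0.43 and the homing selectin Sell at -1.57 ± 0.40. They had more Gzmk (5.31 ± 1.03), Gzmb (4.78 ± 0.89), Ifng (5.08 ± 0.81), Il10, an inhibitory cytokine (6.98 ± 1.07), and the checkpoint receptor Lag3 (3.58 ± 0.80). Of 22 cytotoxic genes 6 rose (10; 1.06), though the list did not move one way (0.58). Erythroid genes were higher, with Gypa, glycophorin A, at 8.38 ± 1.27 and 5 of 8 markers (4.84, 0.55). The count of 741 (578 higher) was 25 in the compared groups only and 480 without Stat5-ko replicate 3. Without replicate 3 Gypa stood at -2.96 (adjusted p = 0.87) and Lag3 did not pass (0.099). Ccr7 and Sell did not pass without replicate 2 (0.16 and 0.11) or 3 (0.12 and 0.073) and stood at -2.98 and -2.50 without replicate 1. Stat5-ko B cells (3 against 9) carried more Aicda, the antibody gene deaminase (5.70 ± 0.69, adjusted p = 1.5e-04), S1pr2 (5.54 ± 0.80), Fas (4.76 ± 0.66) and Rgs13 (4.79 ± 0.73), and more proliferation genes (7 of 23, 19; 1.91, 0.037), Ccnb2 by 3.24 ± 0.53. All 8 erythroid markers were higher when adjusted over the list alone (5.25, fry adjusted p = 0.22, and 0.027 with the replicate block). Of 155 genes 129 were higher, with 50 under the block, 0 with the block in the compared groups (edgeR; 1578 at an unadjusted p under 0.05), 62 without Stat5-ko replicate 1 and 245 without replicate 3. Their ISG list had an adjusted p of 0.061, and 0.027 with the block. Stat5-ko macrophages (3 against 21, only 1 of the same research group) had less of the immediate early genes Nr4a1 (-3.43 ± 0.86) and Jun (-3.13 ± 0.74; list -2.20, 0.020; 0.18 with the block), the STAT6 target Ccl24 (-4.53 ± 1.12; list -0.81, 0.0025) and lysozyme Lyz2 (-2.22 ± 0.59). The erythroid factor Gata1 was at least 620-fold higher. Of 707 genes 167 were higher (188 of 610 with DESeq2's size factors). A fit of the compared groups only called 0, the block 4465, and the fit without Stat5-ko replicate 3 2444 genes. Nr4a1 (adjusted p = 0.057), Lyz2 (0.084) and Ccl24 (0.064) did not pass without replicate 2, nor Nr4a1 without replicate 1 (0.055), and Nr4a1 stood at -5.30 and Ccl24 at -10.94 without replicate 3.

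Stat3-ko macrophages (3 against 21) held more of the NK cell genes Klra8 (5.31 ± 1.19), Nkg7 (4.14 ± 0.82) and Klrc1 (4.74 ± 1.18), with 3 of 10 NK markers higher (9 adjusted over the list alone; 4.68, 0.063). With the replicate block the list had 0.0089 and the cytotoxic list 8.0e-04 (0.17 without it). The 91 genes (74 higher; 43 of 111 with the block) fell to 0 in the compared groups only, and were 0 without Stat3-ko replicate 1, 696 without replicate 2 and 805 without replicate 3. Without replicate 1 Klra8 stood at 1.86 (adjusted p = 1), Klrc1 at 2.61 (1) and Nkg7 at 2.73 (0.71). In CD8 T cells Stat3-ko called 22 genes (14 higher; 3 of 4 higher with DESeq2's size factors, 0 in the compared groups only, 1 without Stat3-ko replicate 1 and 278 without replicate 3), Zpbp (-5.68 ± 1.25) and Swt1 (-2.57 ± 0.60) among the lower ones. Zpbp did not pass without replicate 1 (adjusted p = 0.31) and stood at -10.85 without replicate 2, and Swt1 did not pass without replicate 1 (0.47) or 2 (0.20). In NK cells it called 0 (1202 at an unadjusted p under 0.05, 167 by DESeq2, 4 with the block) and in B cells 0 (547 and 69), where the ISG list had an adjusted p of 0.90, and 0.036 with the block. Stat4-ko called 0 genes in CD8 T cells (73 at an unadjusted p under 0.05, 10 by DESeq2) and macrophages (563 and 134). Stat6-ko called 0 in CD8 T cells (142 and 8; 603 in the compared groups only, 108 with the block) and NK cells (98 and 12). It called 15 in macrophages (13 higher, 261 in the compared groups only, 1893 with the block, 1 without Stat6-ko replicate 2), with Arhgdia, an inhibitor of Rho GTPases (2.23 ± 0.30, adjusted p = 2.2e-05), and the receptor Cd300lf (2.92 ± 0.53) higher and Calm1, a calmodulin, lower (-1.23 ± 0.23). Without Stat6-ko replicate 2 Calm1 (-0.97, adjusted p = 0.33) and Cd300lf (2.60, 0.085) did not pass, and with no research group term Arhgdia stood at -1.72 (0.11).

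The ISG score is the mean log2(CPM + 2) of the 47 ISGs, and the response is its rise over the untreated culture of the same batch, tested against wildtype by 2-sided exact permutation and adjusted over 36 tests. Wildtype CD8 T cells responded by 4.09 ± 0.23 (SD, n = 16) at 1.5 h and 4.67 ± 0.40 (n = 17) at 20 h. Irf9-ko cells reached 0.205 (n = 2, exact adjusted p = 0.0471) and 0.481 (n = 3, 0.0176), and Stat1-ko cells 0.703 and 1.38 (n = 3, 0.0176 at both times). The Irf9-ko cultures had 85.8% to 97.3% mitochondrial counts, so no Irf9-ko culture was left without those over 40%. At 1.5 h the response was also smaller in Tyk2-inact (2.91 ± 0.22, n = 3, exact adjusted p = 0.0176), Tyk2-ko (3.00 ± 0.49, n = 2, 0.0471) and Stat1b-only cells (3.29 ± 0.37, n = 3, 0.0248). By 20 h Tyk2-inact (4.55, exact adjusted p = 0.79) and Tyk2-ko (4.10, 0.12) did not pass. In macrophages the wildtype response was 3.98 ± 0.97 (n = 15) at 1.5 h, against 0.272 in Irf9-ko (exact adjusted p = 0.0481), 1.05 in Stat1-ko (0.0176), 1.68 ± 1.47 in Tyk2-inact (0.0471) and 2.40 in Tyk2-ko (0.103). Stat4-ko macrophages had 5.55 ± 0.19 (exact adjusted p = 0.0252), 1.57 above all wildtype, 1.26 above its group's wildtype (0.097) and 0.73 within batches (0.47). Against wildtype of the same research group no mutant passed. Stat1 and Stat4 mutants faced 8 cultures, Tyk2 mutants 3, allowing no p below 0.1 (inact 0.4, ko 0.7 in macrophages at 1.5 h). There Stat1-ko stood at -3.35 and -3.07 in CD8 T cells and -3.24 in macrophages at 1.5 h (adjusted p = 0.097 each). At 20 h no macrophage mutant passed (wildtype 4.79 ± 1.43; Irf9-ko 1.57, exact adjusted p = 0.12), but 1 wildtype culture stood at 0.563 and the other 14 at 3.65 to 6.51. Without it (chosen after seeing the data) Irf9-ko (0.0429), Stat1-ko (3.03, 0.0235) and Tyk2-inact (3.35, 0.0235) passed. In NK cells (3 against 3, no p below 0.1) wildtype reached 3.36 and 3.79, Tyk2-inact 1.99 and 2.55, and Tyk2-ko 2.23 and 2.62.

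**Figure D3:**
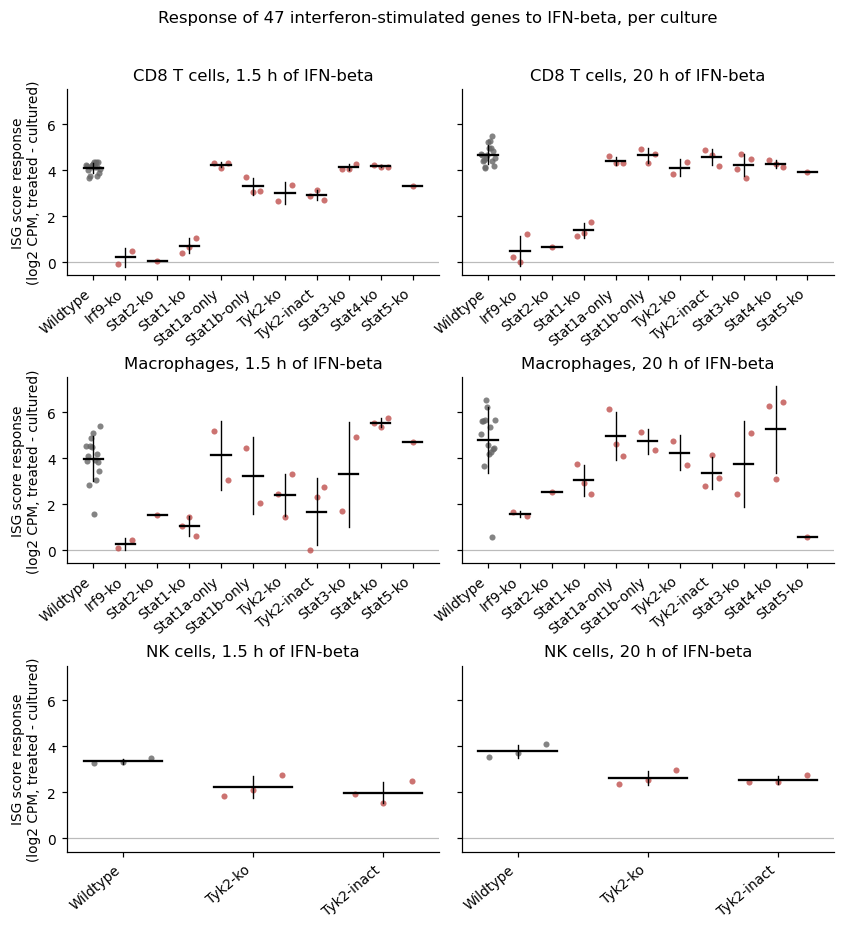
Each point is 1 culture, the ISG score after IFN-beta minus that of the untreated culture of its batch (log2 units), at 1.5 h and 20 h by genotype and cell type, with horizontal bars at the group mean and vertical bars of 1 SD.

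Gene by gene, ISGs had the lowest adjusted p among response differences of Stat1-ko CD8 T cells: Ifit1 differed by -7.65 ± 0.89 at 1.5 h and -4.69 ± 0.80 at 20 h, adjusted p = 4.1e-11, and Oasl1 by -8.12 ± 1.22 at 1.5 h and -6.50 ± 1.12 at 20 h. Oasl1 did not pass in the compared groups without the Stat1-ko replicate 1 culture (adjusted p = 0.98). The ISG list differed in Stat1-ko (median -3.64, 1.7e-07, and -3.18, 2.6e-06), Irf9-ko (-4.32, 2.1e-06, and -5.47, 1.0e-09) and at 20 h in Stat2-ko (-5.69, 8.8e-09). It had 0.82 and 0.50 in Irf9-ko and 0.51 in Stat2-ko in the compared groups only. In Tyk2-inact and Stat1b-only the list at 1.5 h had an adjusted p of 0.80 each, and 0.0014 and 0.046 in the compared groups with the replicate block. In macrophages it differed at 1.5 h in Stat1-ko (-2.90, 0.0027) and Irf9-ko (-3.46, 0.0039). At 20 h the adjusted p was 0.90 and 0.057 (0.039 in Irf9-ko without libraries over 40% mitochondrial counts), and 0.018 and 0.0049 (list means -2.36 and -2.61) in the compared groups with the block. Genes with a different response numbered 2916 in Irf9-ko, 28 in Stat1-ko, 0 in Stat1a-only (534 at an unadjusted p under 0.05; 3 by DESeq2 in the compared groups), 2 in Stat1b-only, 1825 in Stat2-ko (1 culture at 1.5 h), 0 in Stat3-ko (761; 12), 0 in Stat4-ko (825; 0), 414 in Tyk2-inact and 1 in Tyk2-ko CD8 T cells. In macrophages, in the same order, they numbered 3, 479, 196, 143, 2, 11, 830, 483 and 326, but 3 or fewer for each in the compared groups with the block, and the 2 for Stat2-ko rest on 1 untreated culture. Immunoglobulin genes were all 3 in Irf9-ko, both in Stat2-ko and 8 of the 11 in Stat3-ko. In the compared groups only the counts were 25 in Stat1-ko CD8 T cells (92 with the block) and 0 or 1 in the other CD8 T cell mutants, and in macrophages up to 1088 (Stat1-ko).

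By a test of the difference of differences, the ISG deficit of Stat1-ko macrophages differed between culture and fresh cells (fry adjusted p = 0.041), though not in the compared groups with the replicate block (0.38), and in CD8 T cells that of Stat2-ko did (0.0081; 0.81 in the compared groups only). The adjusted p in CD8 T cells went from 0.45 to 0.0016 in the compared groups only in Stat1-ko and from 0.076 to 0.028 with the block there in Tyk2-inact. It went from 0.33 to 0.027 without libraries over 40% mitochondrial counts in Tyk2-ko. For CD8 T cells the counts of genes were 3699 in Irf9-ko, 2 in Stat1-ko, 0 in Stat1a-only (666 at an unadjusted p under 0.05), 2 in Stat1b-only, 3545 in Stat2-ko, 8 in Stat3-ko, 0 in Stat4-ko (547), 561 in Tyk2-inact and 123 in Tyk2-ko, and 0 for each in the compared groups only. For macrophages they were 1452, 600, 588, 408, 219 (on 1 Stat2-ko culture), 1219, 1013, 1571 and 2712 in the same order, and in the compared groups only 0 in Irf9-ko and 1 in Stat3-ko. In the compared groups with the block they were 0 in Stat1-ko, 1 in Stat1a-only, 807 in Stat1b-only, 0 in Stat3-ko, 947 in Stat4-ko, 2105 in Tyk2-inact and 2061 in Tyk2-ko. With DESeq2's size factors the higher genes went from 1832 of 3699 to 3660 of 3921 in Irf9-ko and from 1572 of 3545 to 3746 of 4435 in Stat2-ko CD8 T cells, and from 425 of 561 to 175 of 282 in Tyk2-inact. In macrophages they went from 529 of 1013 to 490 of 1814 in Stat4-ko and from 982 of 1571 to 769 of 1967 in Tyk2-inact. Those factors moved all folds of a comparison together, by up to 3.47 log2 units, and by over 0.1 in 43 of 102 but 3 of 39 with fresh mutants.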

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

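The tests of spread taken from other research groups and the splits within batches were chosen after their result was seen, and the list of muscle genes was written after some had been seen among the largest changes. Irf9-ko and Stat2-ko in fresh CD8 T cells called 1672 and 1599 genes against 28 wildtype libraries, 2 of them of the same research group. Spread taken from the other research groups may account for part of this: edgeR on the 5 libraries of that group alone called 0 and 0 (2620 and 1091 at an unadjusted p under 0.05), though with fewer libraries. Uneven libraries may account for the Stat2-ko count, since on 5000 genes another of the 10 splits of those 5 libraries called 102% as many (489 against 478), whereas for Irf9-ko it was 49.1% (231 against 470), where uneven libraries and the mutation cannot be told apart. Loss of the targeted gene may account for the ISGs: 68.1% and 59.6% of the 47 lay below both wildtype libraries in all 3 mutant libraries, against 27.1% and 24.5% of other expressed genes and 10% by chance. What the mutation adds outside the ISGs stays open.

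RNA of other cells may account for genes foreign to the sorted type, and no biological explanation was tested. Skeletal muscle RNA in Irf9-ko macrophages had a median log2 fold of 9.61 over 11 genes (10 called, 3 also at 5 CPM or more in wildtype), and it lay in replicate 3, with Acta1 at 2380 CPM against 1.43 in wildtype and a sum of 10920 against 765.4 and 926.1 in replicates 1 and 2. Myeloid RNA in Stat5-hyp NK cells had a median of 2.15 over 19 macrophage and neutrophil markers (5 called, 13 at 5 CPM or more in wildtype), Lyz2 reaching 4520 CPM (wildtype mean 219) and Csf1r 1400 (10.5), though in 1 batch the wildtype sum (2834) lay above the mutant (1660), and S100a8 (means 185 and 204) and Ngp (196 and 166) did not follow, which leaves macrophages rather than neutrophils as a candidate source. Erythroid RNA in Stat5-ko macrophages had a median of 3.52 over 8 genes (0 called by edgeR, 6 at 5 CPM or more in wildtype), with sums of 468.4, 5273 and 17230 against 705 in the 1 wildtype library of that group and an adjusted p of 0.47, or 0.0019 with the replicate block (Hbb-bs reaching 5360 CPM against 271).

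Tyk2-mutant CD8 T cells had a smaller ISG response to IFN-beta at 1.5 h than wildtype, and less so at 20 h. A slower response may account for this in Tyk2-inact, where the gain between the 2 times exceeded that of wildtype by 1.04 (3 against 16 cultures, exact permutation p = 0.00619 over 969 splits, 0.0929 after correction over 18 tests). In Tyk2-ko (2 cultures, difference 0.498, exact permutation p = 0.144 over 153 splits) a slower and an evenly smaller response cannot be told apart with so few cultures. The tables argue against a higher untreated score in the mutant: untreated Tyk2-inact cultures differed by -0.3 from wildtype of their group, where the deficit was 1.36. Against wildtype cultures of that group alone, Tyk2-inact stood at -1.36 and -0.59 at the 2 times (exact permutation p = 0.1 each, the smallest that 3 against 3 can give) and Tyk2-ko at -1.27 and -1.04 (0.2 each), so its gain there was smaller than the 0.498 above.

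Differences between cultured and fresh cells in the effect of a mutation were called for 3699 genes in Irf9-ko, 2 in Stat1-ko, 2 in Stat1b-only, 3545 in Stat2-ko, 8 in Stat3-ko, 561 in Tyk2-inact and 123 in Tyk2-ko CD8 T cells, but for 0 in each in the compared groups only. In macrophages Irf9-ko had 1452, Stat1-ko 600, Stat1a-only 588, Stat1b-only 408, Stat2-ko 219 (on 1 culture), Stat3-ko 1219, Stat4-ko 1013, Tyk2-inact 1571 and Tyk2-ko 2712, and in the compared groups only 0 in Irf9-ko and 1 in Stat3-ko. Other splits (below) excluded chance for none tested. A single Stat5-ko culture per cell type, outside the comparisons, answered IFN-beta with an ISG score 3.30 (1.5 h) and 3.91 (20 h) above its untreated culture in CD8 T cells and 4.70 and 0.575 in macrophages, and the wildtype culture of that research group with 4.12 and 4.95, and 4.18 and 0.563. Of 12 groups of 4 to 10 libraries or cultures tested for a value far from the others, 0 had one.

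Labels were drawn again within research groups, across batches (25 splits with the real one, on a random subset of genes for CD8 T cells and macrophages), given as real count/highest other. Chance was excluded, only at a share of splits under 0.05 that was not corrected for the number of comparisons, in B cells Stat5-ko 155/87, in CD8 T cells Stat1-ko 6/1, Stat1b-only 2/1, 1a against 1b 2/0, in dendritic cells Tyk2-ko 2/0, in macrophages Stat1-ko 33/13, Tyk2-inact 7/1, Tyk2-ko 7/1, in NK cells Stat5-hyp 545/356 (fresh), and for wildtype in CD8 T cells IFN-beta at 1.5 h 22/6, IFN-beta at 20 h 13/2, culture 56/7, in macrophages culture 249/47. It was not excluded, with the number of the 25 splits calling as many last, for fresh B cells Stat5-hyp 4/8/3, CD8 T cells Stat1a-only 0/1/25, Stat4-ko 0/12/25, Stat5-hyp 305/307/2, Stat5-ko 194/403/2, Tyk2-inact 25/216/25, Tyk2-ko 33/111/16, ko against inact 140/377/22, dendritic cells Tyk2-inact 1/80/3, ko against inact 0/0/25, macrophages Stat1a-only 6/115/2, Stat1b-only 0/2/25, Stat4-ko 0/16/25, ko against inact 0/0/25, and for wildtype macrophages IFN-beta 1.5 h 62/78/17, 20 h 41/60/18. Nor was it for mutant IFN-beta responses in CD8 T cells Stat1-ko 1/1/5, Stat1a-only 0/1/25, Stat1b-only 0/2/25, Stat3-ko 0/3/25, Stat4-ko 0/4/25, Tyk2-inact 15/50/13, in macrophages Stat1-ko 28/34/5, Stat4-ko 28/40/6, Tyk2-inact 3/23/25, or mutant effects between culture and fresh in CD8 T cells Stat1-ko 0/2/25, Stat1a-only 0/0/25, Stat1b-only 0/0/25, Stat3-ko 0/12/25, Stat4-ko 0/3/25, Tyk2-inact 18/56/17, Tyk2-ko 2/74/22, in macrophages Stat1-ko 13/58/16, Stat1a-only 14/54/24, Stat4-ko 20/53/19, Tyk2-inact 51/74/9, Tyk2-ko 73/81/5. At most 10 splits, too few for a share under 0.05, were possible for fresh B cells Stat3-ko 0/3/10, CD8 T cells Stat3-ko 15/161/9, Stat6-ko 0/2/10, macrophages Irf9-ko 304/160/1, Stat2-ko 105/203/2, Stat6-ko 2/3/3, 1a against 1b 1/1/4, NK cells Stat3-ko 0/336/10, Stat6-ko 0/2/10, Tyk2-inact 12/15/3, Tyk2-ko 11/9/1, ko against inact 1/2/5, and for wildtype in NK cells IFN-beta 1.5 h 590/1/1, 20 h 979/0/1, culture 2169/2/1. Splits with several times the real count, such as 336 in Stat3-ko NK cells, 161 in Stat3-ko CD8 T cells, 115 in Stat1a-only macrophages and 80 in Tyk2-inact dendritic cells, point to a structure of the samples, and labels drawn again within batches, which parts the same pairs, called at most 0, 16, 3 and 0 there. Within batches chance was excluded for Stat5-hyp CD8 T cells (305/204, 25 splits, uncorrected) but not for ko against inact (140/167, 10 of 25), and at most 16 splits, also too few, gave 25/53 in Tyk2-inact and 33/55 in Tyk2-ko CD8 T cells, 33/14 in Stat1-ko macrophages, 155/2 in Stat5-ko B cells and 545/331 in Stat5-hyp NK cells.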

How the results depend on the processing

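Tests chosen after seeing the data were those in the compared groups only, without libraries or cultures over 40% mitochondrial counts, in CPM outside the mitochondrial genome, against wildtype cultures of the same research group and without wildtype culture 12. Over all settings 379 counts of genes stayed within 1.5 times the reported count and 484 did not, and 1336 folds of named genes kept their sign and side of the threshold, 204 fell short of it and 6 turned sign. The ISG list kept its call in 405 tests, gained it in 30 and lost it in 13, and ISG responses kept theirs in 236, lost it in 38, gained it in 3 (without wildtype macrophage 12), moved in 7 and turned sign in 34. Counts that moved and calls that ended or turned follow by setting (1a against 1b compares Stat1 isoforms, ko against inact Tyk2 mutants). Unless the setting itself leaves out libraries or tests other genes, the cause was not tested. The replicate block, DESeq2's test and the fit with no filter were not run on all cultured CD8 T cell and macrophage libraries, nor the block on the culture of NK cells or on CD8 T cell, macrophage and NK comparisons it left without an estimate. Depth was not varied. In simulated counts 0% to 56% of 2-fold changes were recovered, and in cultured macrophages counts of genes rest on 1 (Stat2-ko) to 3 untreated cultures per mutant.

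With DESeq2's size factors in edgeR, fresh CD8 T cells called 4 in Stat3-ko. IFN-beta in CD8 T cells gave 0 in Stat1b-only and 173 in Tyk2-inact. IFN-beta in macrophages gave 0 in Irf9-ko, 295 in Stat1-ko, 361 in Stat1b-only, 4 in Stat3-ko and 190 in Tyk2-ko. Culture of CD8 T cells gave 3 in Stat3-ko and 282 in Tyk2-inact. Culture of macrophages gave 637 in Stat1b-only and 1814 in Stat4-ko. Fresh NK cells had 19 in Tyk2-ko.

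Under DESeq2's test, fresh CD8 T cells called 6246 in Irf9-ko, 77 in Stat1-ko, 5 in 1a against 1b, 14 in Stat1a-only, 16 in Stat1b-only, 5647 in Stat2-ko, 1582 in Stat3-ko, 10 in Stat4-ko, 2063 in Stat5-ko, 8 in Stat6-ko, 1072 in Tyk2-inact, 1641 in ko against inact and 1315 in Tyk2-ko. Fresh macrophages called 2698 in Irf9-ko, 277 in Stat1-ko, 46 in 1a against 1b, 92 in Stat1a-only, 142 in Stat1b-only, 3142 in Stat2-ko, 1038 in Stat3-ko, 134 in Stat4-ko, 2769 in Stat5-ko, 143 in Stat6-ko, 62 in Tyk2-inact, 42 in ko against inact and 83 in Tyk2-ko. There were, in fresh NK cells, 167 in Stat3-ko, 12 in Stat6-ko, 763 in Tyk2-inact, 489 in ko against inact and 844 in Tyk2-ko, in fresh B cells, 69 in Stat3-ko, 190 in Stat5-hyp and 391 in Stat5-ko, in fresh dendritic cells, 1298 in Tyk2-inact, 1346 in ko against inact and 1459 in Tyk2-ko. The sign of Gbp7 turned in Irf9-ko CD8 T cells (37.52).

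Without a filter on low counts, fresh CD8 T cells called 39 in Stat1-ko, 6 in Stat1a-only and Stat6-ko, 4 in Stat1b-only, 107 in Stat3-ko, 7 in Stat4-ko, 1563 in Stat5-hyp, 294 in Tyk2-inact, 837 in ko against inact and 316 in Tyk2-ko. For fresh macrophages it was 249 in Stat1-ko, 73 in 1a against 1b, 153 in Stat1a-only, 67 in Stat1b-only, 396 in Stat3-ko, 109 in Stat4-ko, 53 in Stat6-ko, 77 in Tyk2-inact, 40 in ko against inact and 96 in Tyk2-ko. Fresh NK cells had 110 in Stat3-ko, 953 in Stat5-hyp, 8 in Stat6-ko, 259 in Tyk2-inact, 95 in ko against inact and 333 in Tyk2-ko.

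Without the research group term, fresh CD8 T cells called 3826 in Irf9-ko, 86 in Stat1-ko, 3 in Stat1a-only and Stat1b-only, 3053 in Stat2-ko, 715 in Stat3-ko, 2543 in Stat5-hyp, 1504 in Stat5-ko, 15 in Stat6-ko, 576 in Tyk2-inact and 581 in Tyk2-ko. Macrophages, fresh, had 2139 in Irf9-ko, 1 in Stat1a-only, 1124 in Stat2-ko, 2174 in Stat3-ko, 5111 in Stat5-ko, 80 in Stat6-ko and 59 in Tyk2-ko. CD8 T cells with IFN-beta had 2043 in wildtype at 1.5 h, 911 in wildtype at 20 h, 1 in Stat4-ko and 0 in Tyk2-ko. Macrophages with IFN-beta had 5028 in wildtype at 1.5 h, 4648 in wildtype at 20 h, 193 in Stat1-ko, 91 in Stat1a-only, 55 in Stat1b-only, 5 in Stat3-ko, 280 in Tyk2-inact and 74 in Tyk2-ko. CD8 T cells in culture had 4797 in wildtype, 0 in Stat1b-only and 5 in Stat3-ko. Macrophages in culture had 105 in Stat2-ko, 2810 in Stat4-ko, 3013 in Tyk2-inact and 4895 in Tyk2-ko. There were, in fresh NK cells, 107 in Stat3-ko, 910 in Stat5-hyp, 2 in Stat6-ko, 70 in Tyk2-inact, 0 in ko against inact and 186 in Tyk2-ko, in fresh B cells, 8 in Stat5-hyp and 280 in Stat5-ko. The sign of Arhgdia turned in Stat6-ko macrophages (-1.72).

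With the replicate block, fresh CD8 T cells called 56 in Stat1-ko, 19 in 1a against 1b, 31 in Stat2-ko, 1897 in Stat5-hyp, 108 in Stat6-ko, 43 in Tyk2-inact, 333 in ko against inact and 65 in Tyk2-ko. Fresh macrophages called 3225 in Irf9-ko, 313 in Stat1-ko, 118 in 1a against 1b, 6 in Stat1b-only, 19 in Stat2-ko, 4465 in Stat5-ko, 1893 in Stat6-ko, 126 in Tyk2-inact, 2 in ko against inact and 150 in Tyk2-ko. Fresh NK cells had 4 in Stat3-ko, 2 in Stat6-ko, 84 in Tyk2-inact, 10 in ko against inact and 169 in Tyk2-ko, and fresh B cells 14 in Stat5-hyp and 50 in Stat5-ko, and fresh dendritic cells 4 in Tyk2-inact and 7 in Tyk2-ko, and NK cells with IFN-beta 1169 in wildtype at 1.5 h and 2578 in wildtype at 20 h. The sign of Cd3g turned in Stat2-ko CD8 T cells (-0.11). The sign of Acta1 turned in Irf9-ko macrophages (-0.080).

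In the compared groups only, fresh CD8 T cells called 0 in Irf9-ko, Stat2-ko, Stat3-ko and ko against inact, 136 in Stat1-ko, 145 in 1a against 1b, 14 in Stat1a-only, 19 in Stat1b-only, 448 in Stat5-hyp, 25 in Stat5-ko, 603 in Stat6-ko, 6 in Tyk2-inact and 5 in Tyk2-ko. For fresh macrophages it was 5 in Irf9-ko, 25 in 1a against 1b, 3 in Stat1b-only, 19 in Stat2-ko, 0 in Stat3-ko, Stat5-ko and ko against inact, 261 in Stat6-ko, 85 in Tyk2-inact and 70 in Tyk2-ko. Responses of CD8 T cells differed for 0 in Irf9-ko, Stat1b-only, Stat2-ko, Tyk2-inact and Tyk2-ko and 1 in Stat3-ko. Responses of macrophages differed for 120 in wildtype at 1.5 h, 113 in wildtype at 20 h, 0 in Irf9-ko, 1088 in Stat1-ko, 368 in Stat1a-only, 5 in Stat2-ko and 2 in Stat3-ko. Cultured against fresh CD8 T cells gave 0 in Irf9-ko, Stat1-ko, Stat1b-only, Stat2-ko, Stat3-ko, Tyk2-inact and Tyk2-ko. Cultured against fresh macrophages gave 5304 in wildtype, 0 in Irf9-ko, 367 in Stat1-ko, 1 in Stat3-ko and 3505 in Tyk2-inact. There were, in fresh NK cells, 232 in Stat5-hyp, 2 in Tyk2-inact, 0 in ko against inact and 5 in Tyk2-ko, in fresh dendritic cells, 1 in Tyk2-ko, in NK cells with IFN-beta, 520 in wildtype at 20 h.

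In the compared groups with the block, fresh CD8 T cells called 280 in 1a against 1b, 49 in Stat1a-only, 34 in Stat1b-only, 0 in Stat3-ko and ko against inact, 1 in Stat4-ko, 523 in Stat5-hyp, 8 in Stat5-ko, 601 in Stat6-ko, 4 in Tyk2-inact and 3 in Tyk2-ko. Macrophages, fresh, had 38 in Stat1-ko, 71 in 1a against 1b, 33 in Stat1a-only, 6 in Stat1b-only, 3 in Stat3-ko, 1091 in Stat6-ko, 107 in Tyk2-inact, 0 in ko against inact and 94 in Tyk2-ko. IFN-beta in CD8 T cells gave 0 in Irf9-ko, Tyk2-inact and Tyk2-ko, 92 in Stat1-ko and 5 in Stat1b-only. IFN-beta in macrophages gave 100 in wildtype at 1.5 h, 133 in wildtype at 20 h, 0 in Irf9-ko and Tyk2-inact, 3 in Stat1-ko, Stat3-ko and Stat4-ko and 1 in Stat1a-only, Stat1b-only and Tyk2-ko. Culture of CD8 T cells gave 0 in Stat1-ko, Stat1b-only, Stat3-ko, Tyk2-inact and Tyk2-ko. Culture of macrophages gave 0 in Stat1-ko and Stat3-ko, 1 in Stat1a-only and 807 in Stat1b-only. Fresh NK cells had 190 in Stat5-hyp and 0 in Tyk2-inact, ko against inact and Tyk2-ko, and fresh B cells 11 in Stat5-hyp and 0 in Stat5-ko, and fresh dendritic cells 0 in Tyk2-inact and 8 in Tyk2-ko, and NK cells with IFN-beta 1033 in wildtype at 1.5 h and 1877 in wildtype at 20 h.

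In the compared groups under DESeq2, CD8 T cells with IFN-beta called 0 in Irf9-ko, Stat2-ko, Tyk2-inact and Tyk2-ko, 76 in Stat1-ko, 3 in Stat1a-only and 12 in Stat1b-only and Stat3-ko. Macrophages with IFN-beta had 746 in wildtype at 1.5 h, 930 in wildtype at 20 h, 0 in Irf9-ko, Stat2-ko and Stat3-ko, 200 in Stat1-ko, 77 in Stat1a-only, 47 in Stat1b-only, 203 in Stat4-ko, 185 in Tyk2-inact and 103 in Tyk2-ko. CD8 T cells in culture had 300 in Stat1-ko, 398 in Stat1a-only, 884 in Stat1b-only, 5340 in Stat2-ko, 162 in Stat3-ko, 332 in Stat4-ko, 1576 in Tyk2-inact and 1615 in Tyk2-ko. Macrophages in culture had 4737 in wildtype, 3988 in Irf9-ko, 1952 in Stat1-ko, 4483 in Stat1a-only, 5299 in Stat1b-only, 2866 in Stat2-ko, 2427 in Stat3-ko, 4473 in Stat4-ko and 3307 in Tyk2-inact.

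Without libraries over 40% mitochondrial counts, fresh CD8 T cells called 8 in 1a against 1b, 3 in Stat1a-only, 2 in Stat1b-only and 50 in Stat3-ko. CD8 T cells with IFN-beta had 3 in Stat4-ko, 866 in Tyk2-inact and 6 in Tyk2-ko. Macrophages had 41 in Stat1a-only, 14 in Stat1b-only and 3 in Stat3-ko. Cultured against fresh CD8 T cells gave 1 in Stat1-ko, 0 in Stat1b-only and 4 in Stat3-ko, and macrophages 693 in Stat3-ko. With 1 allele code per group, Stat1-ko called 0 in CD8 T cell and 196 in macrophage culture, and Tyk2-ko 1 in fresh dendritic cells. Without the 1 library under 1000000 counts, fresh macrophages called 6 in Stat6-ko.

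Responses of the ISG score turned sign only where the difference from wildtype did not pass in the report. With a prior of 0.5 CPM the response did not pass in CD8 T cells at 1.5 h in Irf9-ko (-4.30) and Tyk2-ko (-1.09) and macrophages at 1.5 h in Irf9-ko (-4.12) and Tyk2-inact (-2.55). It turned sign in CD8 T cells at 1.5 h in Stat3-ko (-0.13) and Stat4-ko (-0.027) and at 20 h in Stat1b-only (0.077) and Tyk2-inact (0.063) and macrophages at 20 h in Stat1b-only (0.11). With the median over the 47 ISGs the response did not pass in CD8 T cells at 1.5 h in Irf9-ko (-5.00), Stat1b-only (-1.004), Tyk2-inact (-0.76) and Tyk2-ko (-0.90) and macrophages at 1.5 h in Irf9-ko (-5.18), Stat1-ko (-4.98), Stat4-ko (1.88) and Tyk2-inact (-2.75). It turned sign in CD8 T cells at 1.5 h in Stat1a-only (-0.26), Stat3-ko (-0.59) and Stat4-ko (-0.40) and at 20 h in Tyk2-inact (0.72) and Tyk2-ko (0.089) and macrophages at 20 h in Stat1a-only (-0.24). In CPM outside the mitochondrial genome the response turned sign in CD8 T cells at 1.5 h in Stat3-ko (-0.033) and macrophages at 20 h in Stat1b-only (0.10). Without cultures over 40% mitochondrial counts the response did not pass in CD8 T cells at 1.5 h in Tyk2-ko (-1.11) and macrophages at 1.5 h in Irf9-ko (-3.79) and Tyk2-inact (-2.39). It turned sign in CD8 T cells at 20 h in Stat1b-only (0.028). Against wildtype of the same research group it did not pass in CD8 T cells at 1.5 h in Stat1-ko (-3.35), Stat1b-only (-0.77), Tyk2-inact (-1.36) and Tyk2-ko (-1.27) and at 20 h in Stat1-ko (-3.07) and macrophages at 1.5 h in Stat1-ko (-3.24), Stat4-ko (1.26) and Tyk2-inact (-1.18). It turned sign in CD8 T cells at 20 h in Stat1b-only (0.19) and macrophages at 1.5 h in Stat1a-only (-0.17) and at 20 h in Stat1a-only (-0.40) and Stat4-ko (-0.10). Within batches (the replicate block) it did not pass in CD8 T cells at 1.5 h in Stat1-ko (-3.35), Stat1b-only (-0.59), Tyk2-inact (-1.36) and Tyk2-ko (-1.23) and at 20 h in Stat1-ko (-3.12) and macrophages at 1.5 h in Stat1-ko (-3.26), Stat4-ko (0.73) and Tyk2-inact (-1.18). It turned sign in CD8 T cells at 1.5 h in Stat4-ko (-0.044) and at 20 h in Stat1b-only (0.22) and macrophages at 20 h in Stat1a-only (-0.0042) and Stat4-ko (-0.51). Here 2 to 4 batches allow no p below 0.125, 3 against 3 cultures 0.1 and 3 against 8 cultures 0.012.

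When 1 replicate was left out (its number in parentheses, none where 3 or more gave the value), fresh CD8 T cells called 1055 (1) to 2370 (3) in Irf9-ko, 10 (1) to 14 (3) in Stat1-ko, 391 (3) to 3166 (1) in Stat2-ko, 1 (1) to 278 (3) in Stat3-ko, 480 (3) to 554 (1) in Stat5-ko and 1 (Stat1b-only 1 and Stat1b-only 2) to 2 in 1a against 1b. Fresh macrophages called 261 (3) to 1696 (2) in Irf9-ko, 29 (1) to 160 (2) in Stat1-ko, 2 (1) to 7 (3) in Stat1a-only, 1 (1) to 2 (2 and 3) in Stat1b-only, 102 (3) to 3980 (1) in Stat2-ko, 0 (1) to 805 (3) in Stat3-ko, 0 (1) to 1 (2 and 3) in Stat4-ko, 655 (2) to 2444 (3) in Stat5-ko, 1 (2) to 15 (3) in Stat6-ko, 23 (2 and 3) to 29 (1) in Tyk2-inact and 0 to 1 (Stat1a-only 1 and Stat1a-only 2) in 1a against 1b. Fresh NK cells called 0 (2 and 3) to 1 (1) in Stat3-ko, 358 (1) to 638 (4) in Stat5-hyp, 3 (2) to 9 (3) in Tyk2-inact, 0 (1) to 10 (2 and 3) in Tyk2-ko and 0 to 6 (Tyk2-ko 3) in ko against inact, B cells 0 (2 and 3) to 4 (1) in Stat5-hyp and 62 (1) to 245 (3) in Stat5-ko, and dendritic cells 1 to 3 (1) in Tyk2-inact. Treated NK cells called 541 (untreated 3) to 882 (untreated 1) in wildtype at 20 h, and cultured ones 1141 (cultured 2) to 1369 (cultured 1) in wildtype. In the compared groups only, where a lone culture was assumed to vary like the other groups, differences in IFN-beta response numbered 10 (1) to 18 (3) in Stat1-ko, 0 (2 and 3) to 6 (1) in Stat1b-only, 0 (1 and 4) to 1 (2 and 3) in Stat3-ko and 0 in Irf9-ko, Stat2-ko, Tyk2-inact and Tyk2-ko in CD8 T cells. They numbered 0 (1 and 2) to 1 (3) in Stat1-ko, 1 (1) to 6 (2) in Stat2-ko, 4 (3) to 12 (2) in Stat3-ko, 0 (1 and 2) to 274 (3) in Tyk2-inact, 0 (1 and 2) to 2 (3) in Tyk2-ko and 0 in Stat1a-only, Stat1b-only and Stat4-ko in macrophages. Culture differences numbered 0 to 6 (cultured 3) in Irf9-ko, 0 to 5 (cultured 2) in Stat1-ko, 0 to 2 (cultured 1 and cultured 2) in Stat1a-only, 0 to 119 (cultured 1) in Stat1b-only, 0 to 1 (fresh 3) in Stat3-ko, 0 to 7 (cultured 1) in Stat4-ko, 0 (cultured 1 and cultured 3) to 1 (cultured 2) in Tyk2-inact, 0 (cultured 1 and cultured 3) to 1 (cultured 2) in Tyk2-ko and 0 in Stat2-ko in CD8 T cells. Macrophages had 0 to 992 (cultured 2) in Irf9-ko, 0 (fresh 1 and fresh 2) to 359 (cultured 1) in Stat1-ko, 4 to 476 (cultured 3) in Stat1a-only, 270 (cultured 1) to 420 (fresh 2) in Stat1b-only, 0 (fresh 1) to 1672 (fresh 3) in Stat2-ko, 0 (cultured 2 and cultured 3) to 5 (fresh 2) in Stat3-ko, 9 (fresh 1) to 660 (cultured 1) in Stat4-ko and 2261 (cultured 3) to 3802 (cultured 1) in Tyk2-inact. The ISG response, without a test where 1 culture was left, ran from -4.17 (2) to -3.59 (1) in Irf9-ko 1.5 h, -1.01 (1) to -0.69 (2) in Stat1b-only 1.5 h, -0.048 (3) to 0.071 (1) in Stat3-ko 1.5 h, -1.43 (2) to -0.74 (1) in Tyk2-ko 1.5 h, -0.17 (1) to 0.15 (2) in Stat1b-only 20 h and -0.26 (1) to 0.077 (3) in Tyk2-inact 20 h in CD8 T cells. In macrophages it ran from -0.93 (1) to 1.20 (2) in Stat1a-only 1.5 h, -1.93 (1) to 0.45 (2) in Stat1b-only 1.5 h, -2.29 (2) to 0.92 (1) in Stat3-ko 1.5 h, 1.47 (3) to 1.66 (2) in Stat4-ko 1.5 h, -2.84 (3) to -1.47 (1) in Tyk2-inact 1.5 h, -3.52 (12) to -3.14 (2) in Irf9-ko 20 h, -2.12 (1) to -1.45 (3) in Stat1-ko 20 h, -0.42 (1) to 0.60 (3) in Stat1a-only 20 h, -0.44 (1) to 0.34 (2) in Stat1b-only 20 h, -2.34 (2) to 0.29 (1) in Stat3-ko 20 h, -0.11 (3) to 1.56 (2) in Stat4-ko 20 h and -1.83 (2) to -1.15 (1) in Tyk2-inact 20 h. Among genes, Fut4 ran from -0.085 (1) to 7.46 (2) in Irf9-ko CD8 T cells and Gypa ran from -2.96 (3) to 8.91 (1) in Stat5-ko CD8 T cells. In 32 further results no left-out library moved the value.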
